A study of Mus musculus with 8 samples.

How the data were processed

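Polyadenylated RNA from whole-tissue sections of the distal ileum was sequenced in 8 mice, 1 library per mouse. The mice formed 4 littermate couples, each with a Cftr null (KO) animal and a sex-matched wild-type (WT) control on the FVB strain. Per the labels, couples 1 and 3 were female and couple 2 male, and a further couple, labelled female, received ciprofloxacin and metronidazole in the drinking water. Per the labels' protocols, the members of a couple were sampled within 20 min of each other, between 12 and 14 h, and the laxative given to all mice had been stopped for more than 4 days. The sex of the antibiotic couple could not be checked, because Xist and Ddx3y were both listed at 0 in its libraries.

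Per the series' design text, reads came from an Illumina HiSeq or an Ion Proton sequencer and were mapped by the authors to GRCm38 (annotation release 76) with CLC Genomics Workbench 7.5 at default settings. Which library ran on which instrument, the counting rule and the normalization are not given in the sources used here. The deposited table holds 41128 gene symbols with a non-integer value per library. The unit of the deposited values is not named and was taken as RPKM, a value scaled by library size and gene length. The library sums were 346794 to 397082, unlike the fixed sum of TPM, and the log2 values of expressed protein-coding genes fell with log2 exon length in each library (slopes -0.54 to -0.36).

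The sorted values of the 4 libraries of couples 1 and 2 were identical, the pattern that quantile normalization leaves. Couple 3 and the antibiotic couple each shared most of their distinct values within the couple and none with the other couples. The authors' values were therefore treated as 3 separately normalized sets. Libraries of couples 1 and 2 listed 20896 genes above 0, those of couple 3 listed 11912 and 11931, and those of the antibiotic couple listed 13672 and 13749, so a value of 0 was not read as absence. Read depth is unknown: quantile normalization removes the steps that single reads would leave, and no counting interval was computed.

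The WT antibiotic column had faults on a scale not seen in the other columns. In it, 376 genes shared 48 non-zero values, often with alphabetical neighbours, and 233 of them had the value 7.26. Each other column had 18 to 26 genes that shared a non-zero value. Some of the ties join 1 symbol written in 2 letter cases, such as Fmn1 and FMN1, and occur in the KO littermate too, so they are not faults of this column. A further 45 genes were listed at 0 while the KO littermate had at least 1, and 2 genes (Fth1 and Tpi1) lay over 3 log2 units below both the littermate and the untreated range. These 423 genes were left out of each comparison that uses the antibiotic couple, a rule written after the values were seen. The rule on values of 0 works in 1 direction and was not shown to mark a fault for each gene: 10, 7 and 21 genes were listed at 0 in WT with at least 1 in KO in untreated couples 1, 2 and 3. Results with these 45 genes kept are given where they differ. Wrong values that meet none of these rules would remain, so single-gene values of that column are less certain than those of the other 7 libraries.

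Values were analysed as log2(value + 1), which understates the change of low genes. Genes with a value of at least 1 in at least 3 libraries were tested with limma 3.58.1 (moderated statistics with a trend in the prior variance) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The untreated genotype comparison used 6 libraries without a block, as fixed before the data were examined, along with the gene lists, the naming rule and all alternatives not stated to be added later. The couple numbers mark shared litters per the labels, and littermates deviated together from their group means (correlations across genes 0.62, 0.64 and 0.51 in couples 1, 2 and 3). These correlations cannot separate the litter from a shared normalization set or a shared instrument, which the block would absorb as well. The fit with the couple as a block is therefore printed beside results it changes.

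The antibiotic effect was fitted over all 8 libraries with genotype and treatment as terms, and its dependence on genotype with 1 mean per group. In both, the spread comes mainly from the untreated libraries, and treatment coincides with a couple, its litter and its normalization set. The genotype ratio within the antibiotic couple has no replicate and no test. The median of each gene list there was placed among 10000 random lists of the same size matched on mean level. The random lists were drawn gene by gene, so they ignore correlation between the genes of a list. A percentile is therefore a description and not a test.

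Gene lists for intestinal functions, immune responses and cell types (44 lists) were compared with all other genes by camera with its preset correlation between genes. Camera with an estimated correlation and fry were alternatives, and lists with fewer than 5 tested genes were not tested. The latter were the neutrophil (1 tested gene), mast cell (4), eosinophil and basophil (2) and erythroid (4) lists. A liver list of 32 genes was added after the data were seen.

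Genes named for the untreated comparison were Cftr and, in each direction, the 12 largest fitted changes among called genes with 1 direction in all 3 couples and a mean log2 level at or above the median, leaving out predicted genes. For the antibiotic effect and dependence, the 8 smallest p-values in each direction were named under the same limits. From each list, up to 4 members with the smallest p were named. Of the genes that met these rules, 2 are not reported here. Members of near-identical families (Sprr2, Reg3, H2, immunoglobulin genes) can share reads and are uncertain as single genes.

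On data simulated on the 6 untreated libraries (11717 genes, 200 of them changed, 5 runs), limma without the block recovered 18.2% of changes of 1 log2 unit and 86% of changes of 2 log2 units. The blocked fit recovered 63.4% and 90.4%. The mean number of false calls was 1.2 of 105 without the block and 4.8 of 159 with it. A list of 30 genes shifted by 0.7 log2 units was called in 5 of 5 runs. The simulated noise was independent between genes, and both littermates had the same couple shift. The runs therefore do not show how the list test behaves with correlated genes, and the shared shift favours the blocked fit.

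Positions and exon lengths come from GENCODE mouse release 21, on the authors' assembly GRCm38. Of the 41128 symbols, 36723 (89.3%) had a single entry there. Alternatives covered the couple block, normalization, pseudocount, filter, variance trend, set test and left-out libraries or couples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.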

Results

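Gene expression was measured in whole sections of the distal ileum, less than 6 cm from the ileocecal valve, in 4 Cftr null mice and their 4 wild-type littermates. Cftr encodes the epithelial chloride and bicarbonate channel that is defective in cystic fibrosis. 3 couples were untreated (WT n = 3, KO n = 3). A further couple (1 WT, 1 KO) had 2 antibacterial drugs in the drinking water, metronidazole at 0.5 g/L and ciprofloxacin at 0.3 g/L. Values are the authors' RPKM-like values, normalized in 3 separate sets (couples 1 and 2, couple 3, antibiotic couple), and the read depth behind them is unknown. The comparisons address which ileal transcripts differ between KO and WT mice, and how the genotypes compared in the couple given antibiotics.

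Cftr itself was lower in each KO library than in its littermate. The gene lies on chromosome 6 at 18170687 to 18322768 (plus strand, GRCm38). Its value was 10.8 ± 1.39 in untreated WT and 3.19 ± 0.549 in untreated KO ileum (SD, n = 3 each), a log2 change of -1.50 (SE 0.17, limma adjusted p = 0.007). In the antibiotic couple it was 13.8 in WT and 4.94 in KO. Each value covers the whole gene and does not show from which part of it the remaining RNA comes.

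Genes significantly higher in untreated KO ileum included the epithelial defence genes Dmbt1 and Duoxa2, the antigen presentation gene H2-Eb1 and the interferon-induced gene Ubd. Genes significantly lower included the lactase gene Lct, the retinol saturase gene Retsat and the drug-metabolizing cytochrome gene Cyp2d26. Of 11717 tested genes, 135 were higher and 118 were lower in KO (limma). Of these, 112 and 94 changed at least 2-fold, and all 253 had the same direction in each of the 3 couples. Among all tested genes 60.64% had 1 direction in the 3 couples. The calls come from these same libraries and favour such genes, so the shared direction is not independent support. The median log2 change of all tested genes was -0.01. With the couple as a block, 984 genes were higher and 1161 lower, and all 253 were among them (205 higher and 186 lower at least 2-fold). The blocked counts were 201 and 263 without couple 1, 200 and 221 without couple 2, and 248 and 275 without couple 3. Without the block, leaving out any 1 couple gave 0 higher and 0 lower. Without the filter on low values the counts were 7 and 4. Leaving out 1 library without the block gave 74 higher and 44 lower without WT of couple 1, 46 and 28 without KO of couple 1, 72 and 69 without WT of couple 2, 56 and 35 without KO of couple 2, 41 and 21 without WT of couple 3, and 53 and 53 without KO of couple 3.

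Among called genes with a mean log2 level at or above the median, those with the 12 largest rises included Dmbt1, Duoxa2 and Ubd. Dmbt1, a mucosal scavenger glycoprotein, went from 33.8 ± 14 in WT to 293 ± 49 in KO (SD, n = 3 each; log2 change 3.14, SE 0.30, adjusted p = 0.00478, higher in 3 of 3 couples). Duoxa2, the maturation factor of the hydrogen peroxide producing oxidase DUOX2, went from 3.61 ± 0.678 to 68.8 ± 37.1 (log2 change 3.80, SE 0.35). Ubd, an interferon-induced ubiquitin-like modifier, went from 1.93 ± 0.902 to 47 ± 21.2 (log2 change 3.96, SE 0.38). Upp1, a uridine phosphorylase, rose from 48.4 ± 12 to 272 ± 40.1, and H2-Eb1, an MHC class II beta chain, from 5.72 ± 1.6 to 32.3 ± 8.25. The small proline-rich genes Sprr2a3 and Sprr2a2, near-identical paralogs, had log2 changes of 4.24 and 3.72. The other rises among these 12 were those of B3gnt7 (2.75), a glycosyltransferase, Irgm2 (2.61), an immunity-related GTPase, and the immunoglobulin kappa variable genes Igkv4-70 (2.60), Igkv6-15 (2.47) and Igkv1-135 (2.31).

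Under the same limit on the mean level, the 12 largest falls included Lct, Pdk4 and Cubn. Lct, the brush border enzyme lactase (chromosome 1, 128284756 to 128328318, minus strand), went from 110 ± 18.4 in WT to 10.8 ± 1.79 in KO (SD, n = 3 each; log2 change -3.23, SE 0.20, adjusted p = 0.00136, lower in 3 of 3 couples). Pdk4, a kinase that inhibits pyruvate dehydrogenase, went from 37.7 ± 30.4 to 1.4 ± 0.952 (log2 change -3.78, SE 0.54, adjusted p = 0.0185). Cubn, the intestinal receptor for the intrinsic factor and vitamin B12 complex, went from 130 ± 61.7 to 9.91 ± 1.69 (log2 change -3.49, SE 0.33). The pyrimidine nucleoside enzymes Cda and Tymp had log2 changes of -2.77 and -2.54, and Retsat, a retinol saturase, of -2.52. The other falls among these 12 were Ces2a (-3.10), Tm4sf4 (-2.71), Cyp2d26 (-2.70), Mep1a (-2.52), Cyp2c65 (-2.46) and Acaa1b (-2.34). Some called genes of lower mean level had changes as large, among them Fgf15 (-4.24), Slc28a1 (-3.22), Slc6a14 (3.75) and Plet1 (3.25).

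Of the 24 genes named above, 13 were called whichever 1 library was left out, namely Ubd, Duoxa2, Sprr2a2, Dmbt1, Upp1, H2-Eb1, Cubn, Lct, Cda, Tm4sf4, Cyp2d26, Tymp and Retsat. The other 11 missed the threshold in at least 1 of these fits. Of the 24, 10 were lost without KO of couple 1, 7 without KO of couple 2, 4 without KO of couple 3, 7 without WT of couple 1, 5 without WT of couple 2 and 7 without WT of couple 3, with adjusted p-values of at most 0.139 and no change of direction.

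**Figure D1:**
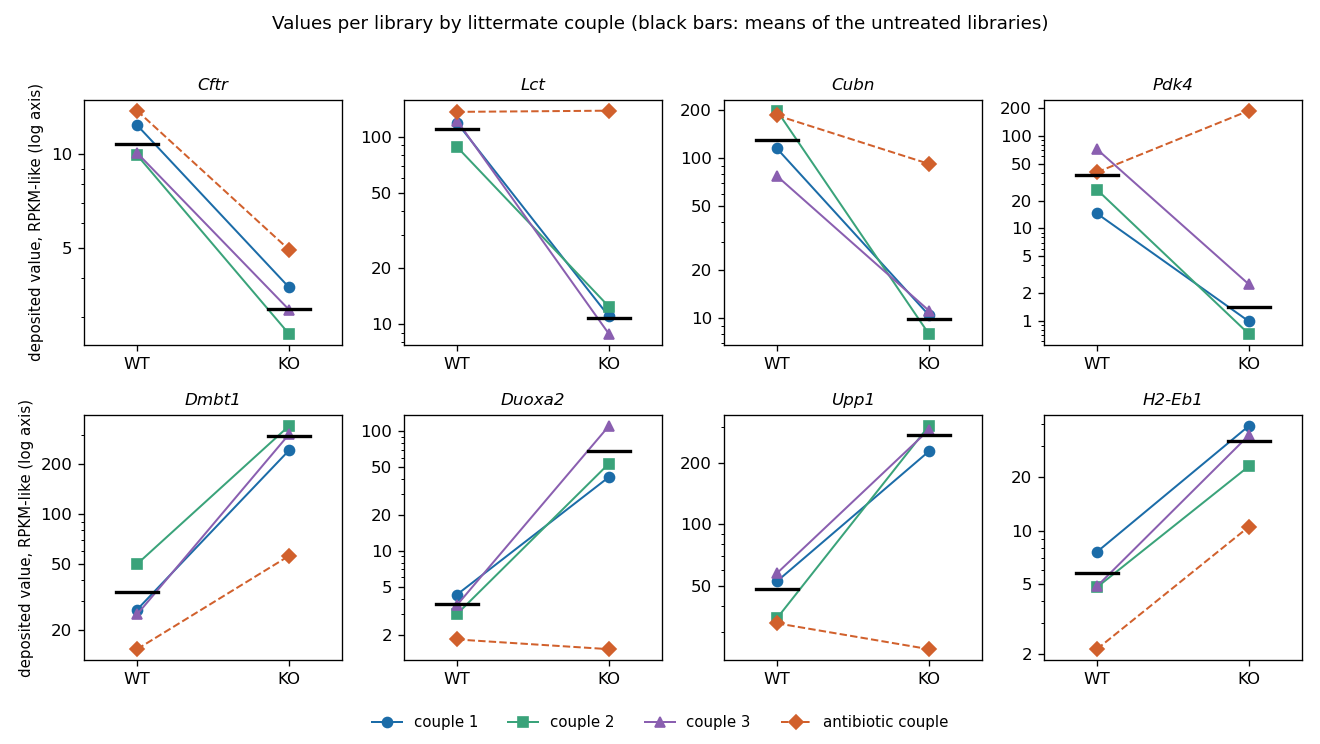
Deposited RPKM-like values (vertical log axis) of 8 genes in the WT and KO library of each couple, joined by a line per couple, dashed for the antibiotic couple; black bars are means of the 3 untreated libraries of a genotype. Lct was 88.4 or more in untreated WT and at most 12.4 in untreated KO libraries, and 136 and 138 in the WT and KO libraries with antibiotics.

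Of 40 lists tested by camera, 15 were higher and 15 lower in untreated KO than the other genes (16 and 15 with the couple block). None was called with an estimated correlation between genes (adjusted p = 0.229 to 0.456 for the 30 lists, and 0.414 to 0.664 with the block). Fry, which asks whether a list's genes move one way, called 7 lists higher and 5 lower. The higher ones were MHC class I and II, antimicrobial, cytokine, T and NK cell, unfolded protein response and ribosomal protein genes. The lower ones were PPARA target, xenobiotic, retinoid, bile acid and ion transport genes. The other lists called by camera did not pass fry. Lists share members, such as Lct, Cubn and Mep1a.

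Genes of peroxisomal and mitochondrial fatty acid oxidation and other PPARA targets were lower in KO. The median log2 change was -0.69 over 40 tested genes, of which 7 fell and 0 rose over all genes tested (24 fell adjusted over the list alone, and 30 fell with the block; camera adjusted p = 6.5e-16, adjusted p = 0.229 with an estimated correlation). Cyp4a10, a fatty acid hydroxylase, went from 10 ± 5.54 to 0.27 ± 0.14, and Ppara, the nuclear receptor itself, from 19.8 ± 4.76 to 5.14 ± 1.79 (SD, n = 3 each). Aldh3a2, a fatty aldehyde dehydrogenase, had a log2 change of -1.25. Genes of xenobiotic metabolism had a median of -0.88 over 53 genes, with 9 lower and 0 higher (25 lower adjusted over the list alone, and 32 lower with the block; adjusted p = 0.229 with an estimated correlation). Ces2b (-1.78) and Ugt2b36 (-1.36) were among the falls. In the retinoid list, with a median of -0.67 over 16 genes, 3 fell (9 lower and 1 higher adjusted over the list alone, 9 lower and 2 higher with the block; adjusted p = 0.229 with an estimated correlation). These were Retsat, Adh1 (-1.83) and Rdh7 (-2.22), which act on retinol and related alcohols.

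Brush border genes of enterocytes had a median log2 change of -0.58 over 40 genes, 4 of which fell, namely Slc28a1, Lct, Cubn and Mep1a (5 lower and 1 higher adjusted over the list alone, 21 lower and 1 higher with the block; adjusted p = 0.267 with an estimated correlation). Slc28a1, a sodium-dependent nucleoside transporter, went from 15.5 ± 3.39 to 0.749 ± 0.126 (SD, n = 3 each; log2 change -3.22, SE 0.19, adjusted p = 0.00136). In the lipid absorption list (median -0.47 over 28 genes), 3 genes fell (8 adjusted over the list alone; 13 lower and 1 higher with the block; adjusted p = 0.267 with an estimated correlation). They were the sterol exporters Abcg5 (-1.16) and Abcg8 (-1.40) and the cholesterol transporter Abca1 (-1.44). The lists of distal (median -0.61, 22 genes, 3 lower, 10 lower with the block) and proximal (median -0.45, 21 genes, 3 lower, 8 lower and 1 higher with the block) small intestine genes were both lower by camera. Each had an adjusted p of 0.229 with an estimated correlation and 0.0507 by fry. The 3 lower genes of the proximal list were Lct, Rdh7 and Fgf15. Fgf15 encodes an ileal hormone, so this list does not mark the proximal part alone. Peptide and amino acid transporters had a median of -0.31 over 18 genes, 1 of them lower (8 lower and 1 higher with the block; adjusted p = 0.416 with an estimated correlation).

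The bile acid list (median -0.37 over 15 genes, 2 lower, 5 lower with the block; adjusted p = 0.229 with an estimated correlation) held the largest single fall of these lists. Fgf15, the ileal hormone that represses hepatic bile acid synthesis, was 39.9, 10.2 and 56.4 in WT and 0.0454, 0.455 and 1.57 in KO libraries of couples 1, 2 and 3 (log2 change -4.24, SE 0.60, adjusted p = 0.0185). Nr0b2, the repressor SHP, fell as well (-2.50, adjusted p = 0.0143). Fabp6, the ileal bile acid binding protein, was 6050 ± 880 in WT and 1370 ± 794 in KO (SD, n = 3 each), with an adjusted p of 0.0623 without the block and 0.0151 with it. Slc10a2, the apical bile acid transporter, was 46.8 ± 9.09 and 103 ± 45.7, with adjusted p = 0.174 and 0.0762 with the block.

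Ion and fluid transport genes had a median of -0.26 over 49 genes (4 lower and 1 higher; 21 lower and 3 higher with the block; 4 lower and 1 higher adjusted over the list alone; adjusted p = 0.229 with an estimated correlation). Besides Cftr, Ano6 (-1.33) and the water channel Aqp1 (-1.58) fell. Slc6a14, an amino acid transporter driven by sodium and chloride, rose from 0.0649 ± 0.0147 to 15.6 ± 11.4 (SD, n = 3 each; adjusted p = 0.00672).

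Antigen presentation genes were higher in KO. In the MHC class II list, with a median log2 change of 1.90, 8 of 12 genes rose and 0 fell (8 adjusted over the list alone; camera adjusted p = 4.92e-12, adjusted p = 0.229 with an estimated correlation). H2-Ab1 went from 91.7 ± 14 to 404 ± 75.4 and H2-DMa, a peptide-loading chaperone, from 11.2 ± 0.584 to 56.2 ± 7.14 (SD, n = 3 each). In the MHC class I list, with a median of 0.50, 4 of 23 genes rose (9 adjusted over the list alone; 11 higher and 1 lower with the block; adjusted p = 0.229 with an estimated correlation). These were the peptide transporter Tap1 (1.81), the immunoproteasome subunits Psmb8 (1.83) and Psmb9 (1.69), and H2-Q7 (1.05).

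Interferon response genes had a median of 0.69 over 46 genes, 14 of them higher and 0 lower (20 higher and 2 lower both adjusted over the list alone and with the block over all genes; adjusted p = 0.229 with an estimated correlation). The median was 0.19 in couple 1, 1.27 in couple 2 and 0.64 in couple 3. Zbp1, a nucleic acid sensor, had a log2 change of 3.17. In the epithelial antimicrobial and acute phase list (median 1.24 over 29 genes), 11 rose (16 higher and 1 lower adjusted over the list alone, and 16 and 1 with the block; adjusted p = 0.229 with an estimated correlation). Besides Duoxa2 and Ubd these included Plet1 (3.25) and Sprr1a (2.43). The lectin Reg3g was 427 ± 375 in WT and 3120 ± 1660 in KO (SD, n = 3 each), with an adjusted p of 0.0882 without the block and 0.0262 with it. The cytokine and chemokine list had a median of 0.28 over 21 genes, with 3 higher (Ccl8, Il18bp and Il33) and 1 lower (Cxcl14). With the block 7 were higher and 2 lower (adjusted p = 0.229 with an estimated correlation).

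Lists of immune cell markers were higher as groups by camera with its preset correlation, with few single calls. By fry, the T and NK cell list passed (adjusted p = 0.0207). The B and plasma cell (0.145), macrophage and dendritic cell (0.13) and lymphoid follicle (0.339) lists did not. T and NK cell genes had a median of 0.95 over 23 genes with 1 higher, Cd3g (11 higher adjusted over the list alone; 6 higher and 1 lower with the block; adjusted p = 0.229 with an estimated correlation). B and plasma cell genes had a median of 0.65 over 27 genes with 3 higher, Prdm1, Derl3 and Mzb1 (7 with the block; adjusted p = 0.312 with an estimated correlation). Their median was 0.45 in couple 1, -1.01 in couple 2 and 2.10 in couple 3. Macrophage and dendritic cell genes had a median of 0.32 over 22 genes with Cd14 higher (5 higher with the block; adjusted p = 0.367 with an estimated correlation), and lymphoid follicle genes of 0.26 over 15 genes with 0 called (2 higher with the block; adjusted p = 0.45 with an estimated correlation). The follicle medians of couples 1, 2 and 3 were 0.21, -0.29 and 1.16, in the same order as those of the B and plasma cell genes.

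The proliferation list had a median of 0.38 over 42 genes, and each of the 42 had a fitted change above 0. None of them passed alone without the block, and 22 rose with it, Ccnd1 and Rrm2 among them (30 adjusted over the list alone with the block; adjusted p = 0.229 with an estimated correlation). Cytosolic ribosomal protein genes also had a median of 0.38, with 72 of 73 above 0, 0 called without the block and 29 higher with it (adjusted p = 0.229 with an estimated correlation). The median log2 change of all genes went from 0.14 in the fifth with the shortest exon length to -0.12 in that with the longest (0.04 to -0.06 in couple 1, 0.19 to -0.16 in couple 2 and 0.12 to -0.14 in couple 3). In the antibiotic couple it was -0.03 for the shortest and for the longest. The unfolded protein response list had a median of 0.29 over 35 genes with Asns and Derl3 higher (11 higher and 1 lower with the block; adjusted p = 0.229 with an estimated correlation). Cholesterol biosynthesis had a median of 0.43 over 27 genes with 0 called (7 higher with the block; adjusted p = 0.374 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median of 0.19 over 66 genes with 0 called (1 with the block; adjusted p = 0.45 with an estimated correlation). Glycolysis genes had a median of 0.32 over 24 genes with 1 higher (7 higher and 2 lower with the block; adjusted p = 0.416 with an estimated correlation).

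Stromal and vascular lists were lower by camera with its preset correlation, with no single call without the block. Fry did not call them (adjusted p = 0.324 for extracellular matrix, 0.234 for smooth muscle and 0.11 for endothelium). The medians were -0.50 for extracellular matrix (28 genes), -0.30 for smooth muscle (24 genes) and -0.40 for endothelium (18 genes; 2, 3 and 4 genes lower with the block), with adjusted p = 0.456, 0.44 and 0.367 with an estimated correlation. In couple 1 the extracellular matrix and smooth muscle medians were 0.16 and 0.08. Enteric neuron and glia genes had a median of -0.47 over 10 genes with Prph lower and Tac1 higher (1 higher and 5 lower with the block; adjusted p = 0.367 with an estimated correlation). Circadian clock genes had a median of -0.34 over 18 genes with 0 called (6 lower with the block; adjusted p = 0.229 with an estimated correlation). The Paneth cell list (median 0.34, 29 genes) had an adjusted p of 0.0674 by camera and 0.0193 with the block, where 7 genes were higher and 3 lower. The lists of goblet cell and mucus genes (median -0.05, camera adjusted p = 0.91), stem cells (-0.03, adjusted p = 0.747), tuft cells (0, adjusted p = 0.747), colon genes (0.09, adjusted p = 0.696), enteroendocrine cells (-0.34, adjusted p = 0.137), adipocytes (-0.33, adjusted p = 0.146), pancreatic acinar cells (-0.52, adjusted p = 0.146), heat shock and immediate early genes (0.13, adjusted p = 0.143) and NRF2 and glutathione genes (0.21, adjusted p = 0.101) did not pass.

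**Figure D2:**
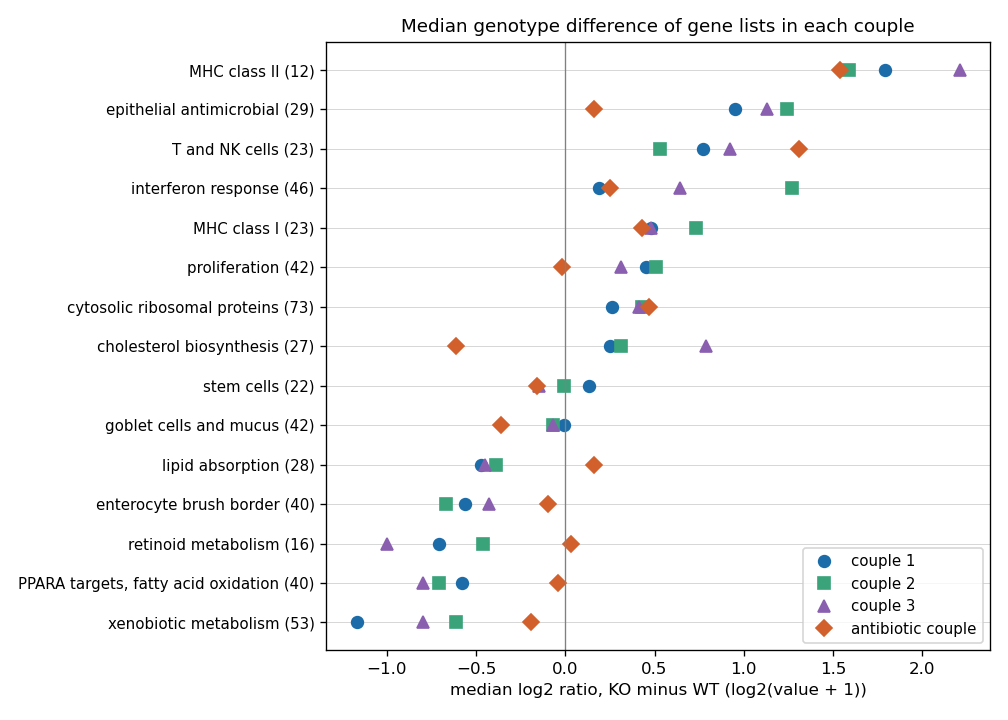
Median log2 ratio of KO over WT (horizontal axis, log2(value + 1)) of 15 gene lists in each untreated couple and in the antibiotic couple, with the number of genes tested over the untreated libraries in parentheses. The MHC class II median was 1.79, 1.59 and 2.21 in couples 1, 2 and 3 and 1.54 with antibiotics, while the PPARA target median was -0.58, -0.71 and -0.80 and then -0.04.

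In the couple given antibiotics, the median KO over WT log2 ratios of the PPARA target and brush border lists were near 0, while those of the MHC class II and lymphocyte lists were well above it. Single members went both ways, such as Pdk4 (2.19) and Cyp4a10 (-1.4) among PPARA targets and Slc28a1 (0.4) and Cubn (-1) among brush border genes. The median KO over WT log2 ratio was 1.54 for MHC class II (11 genes), 1.31 for T and NK cell genes, 2.08 for B and plasma cell genes, 1.11 for lymphoid follicle genes, 0.25 for interferon response genes, 0.28 for cytokines and chemokines, 0.43 for MHC class I and 0.47 for ribosomal protein genes (53 genes), each at percentile 100, as rounded, of the matched random lists. With pseudocounts of 0.1 and 5 in place of 1, the medians were 2.06 and 1.03 for MHC class II, 2.2 and 0.62 for T and NK cell genes, 3.23 and 1.2 for B and plasma cell genes, and 1.53 and 0.44 for lymphoid follicle genes. They were 0.42 and 0.11 for interferon response genes, 0.32 and 0.17 for cytokines and chemokines, and 0.20 and 0.04 for the antimicrobial list, which had 0.16 with a pseudocount of 1 (percentile 99.9). The median was -0.04 for PPARA targets (percentile 48.7), -0.10 for brush border genes (percentile 16.2), 0.03 for retinoid genes (percentile 82.33) and -0.02 for proliferation (percentile 63). It was -0.19 for xenobiotic genes (percentile 0.02). Lipid absorption genes, with a median of -0.47 in untreated mice, had 0.16 in the antibiotic couple (percentile 99.62). Distal small intestine (-0.47), adipocyte (-1.20), cholesterol biosynthesis (-0.61), circadian clock (-0.43) and goblet cell genes (-0.36) lay below all or nearly all random lists, and bile acid genes had a median of -0.28 (percentile 0.17), with Fabp6 at -3.43. Of the 253 called genes, 247 had a usable ratio, and 177 of these (71.7%) had the direction seen in untreated mice, 97 of 130 higher and 80 of 117 lower, while 69 had the opposite direction and 1 a ratio of 0. Of the 250 top genes of 2 untreated couples, 96.4 to 97.2% had the same direction in the untreated couple held out and 65.6 to 69.6% in the antibiotic couple. For the called genes with a usable ratio, the median in the antibiotic couple was 0.35 for those called higher and -0.19 for those called lower. The medians of all called genes in untreated mice were 1.53 and -1.41. The values from the antibiotic couple are ratios of 2 libraries without replicates. Lists not called in untreated mice also had extreme percentiles, such as NRF2 and glutathione (median -0.27, percentile 0.01) and tuft cell genes (0.27, percentile 99.66). An extreme percentile thus does not set a list apart here. The random lists ignore correlation between genes, so an extreme percentile does not show a difference beyond that between mice. The B and plasma cell median, for example, ranged from -1.01 in couple 2 to 2.1 in couple 3 of the untreated mice.

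Lct was 136 in WT and 138 in KO with antibiotics, and Cda 101 and 124. Pdk4 was 40.5 and 188, Upp1 32.9 and 24.6, and Duoxa2 1.82 and 1.51. H2-Eb1 was 2.13 and 10.5 and Dmbt1 15.4 and 56. Fgf15 was 18.6 and 37.2.

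With the doubtful WT antibiotic values left out, no gene passed the test of whether the genotype effect depended on antibiotics (limma, 11520 genes, smallest adjusted p = 0.0956, 483 genes at an unadjusted p under 0.05). With the couple as a block the count was also 0 (smallest adjusted p = 0.0862, 1850 genes at an unadjusted p under 0.05). With the 45 genes listed at 0 in the WT antibiotic library kept, 5 were higher and 1 lower: Eif4a1, Eif4a3, H2-T3 and Mta2, each listed at 0 there, and Slc28a1 and Plet1 (both adjusted p = 0.0337). The log2 dependence of Slc28a1 was 3.62 in both fits. Slc28a1 and Plet1 passed only because the doubtful genes listed at 0 ranked ahead of them in the adjustment. Among ratios higher with antibiotics, the smallest p-values belonged to Slc28a1 (3.62, adjusted p = 0.0956), Lct (3.25, adjusted p = 0.269) and Cda (3.06, adjusted p = 0.269), followed by Adnp, Igkv2-137, Vwa1, Fbp1 and Slc47a1 (adjusted p = 0.269 to 0.28). Those in the other direction included the bile acid transporter Slc10a2 (-4.04), the immediate early gene Fos (-3.76), Upp1 (-2.89), Nudt5 (-2.15), Duoxa2 (-3.97), Id1 (-2.49) and Trim15 (-1.65), with adjusted p = 0.275 to 0.383. Slc10a2 was 67.1 in WT and 7.53 in KO with antibiotics. Plet1, not named above because of the limit on mean level, also went in this direction (-3.76), with the same adjusted p as Slc28a1. For Fos, Adnp and Igkv2-137 the WT antibiotic value (109, 3.85 and 1.04) lay apart from the other 7 libraries in a column known to hold faults.

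The glutathione transferase genes Gstm1, Gsta1 and Gsta3 and the fatty acid translocase gene Cd36 were higher in both antibiotic libraries than in each untreated library, and Nos2 was lower, but none of these was called with the couple as a random block. Over all 8 libraries, 15 genes were higher and 3 lower with antibiotics (limma, 11520 genes, 2240 at an unadjusted p under 0.05). With the couple as a random block (correlation 0.6) the count was 0 (742 at an unadjusted p under 0.05, smallest adjusted p = 0.18). Without the filter on low values it was also 0. Leaving out 1 untreated library gave 5 to 14 higher and 1 to 6 lower, with 8 and 1 without WT of couple 1, 6 and 1 without KO of couple 1, 14 and 6 without WT of couple 2, 7 and 2 without WT of couple 3, and 5 and 4 without KO of couple 3. Treatment coincides with a couple and a normalization set here, so these differences cannot be assigned to the drugs.

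The rises included the glutathione transferases Gstm1 (log2 change 1.90), Gsta3 (3.31) and Gsta1 (2.57), Akr1c19 (2.41), the carboxylesterase Ces1g (3.66), the fatty acid hydroxylase Cyp4a10 (4.52), the glucose transporter family member Slc5a4b (2.75) and the fatty acid translocase Cd36 (3.57), with adjusted p = 0.00773 to 0.0304. Of the named falls, Nos2, the inducible nitric oxide synthase (-3.88, SE 0.28, adjusted p = 0.00376), and H2-DMa (-1.42, adjusted p = 0.0387) passed. Nos2 was 22.3 ± 7.89 in untreated WT and 79.6 ± 17.2 in untreated KO (SD, n = 3 each), and 0.862 and 3.43 with antibiotics. Tap1, H2-DMb1, Psmb8, Timm10, Zc3h12a and Reg3g did not pass, with log2 changes of -3.72 to -0.92 and adjusted p = 0.0676 to 0.0931. Reg3g was 25.9 in WT and 192 in KO with antibiotics.

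Of the 40 lists, 11 were higher and 10 lower with antibiotics by camera, and none with an estimated correlation (adjusted p = 0.262 to 0.623). With quantile normalization over all libraries, 10 were higher and 16 lower. Xenobiotic metabolism (median 1.09, 5 of 54 genes higher), PPARA targets (0.65, 1 of 40 higher), retinoid metabolism (0.57) and lipid absorption (0.55, 1 of 27 higher) were higher, each with adjusted p = 0.262 with an estimated correlation. MHC class II (-1.08, 1 of 11 lower) and Paneth cell genes (-0.74) were lower with adjusted p = 0.262, interferon response genes (-0.97) with adjusted p = 0.322, and the antimicrobial (-0.71, 1 of 28 lower) and proliferation (-0.56) lists with adjusted p = 0.374, all with an estimated correlation. Albumin RNA, a liver transcript, was 397 and 357 in the antibiotic WT and KO libraries, 110 in KO of couple 1, 10.6 in KO of couple 3, and at most 0.163 in the other 4 untreated libraries. In couples 1, 2 and 3, 26, 3 and 10 of the 32 liver genes were at 1 or more in KO, against 2, 3 and 0 in WT. One of them, Hamp, was called higher in untreated KO (log2 change 2.82, limma adjusted p = 0.0127). It was 6.95 in KO of couple 2, where albumin was 0.0419. Whether liver RNA adds to the untreated genotype differences was not tested.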

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

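The 2 liver tests, the positions of held-out libraries and the fit that keeps the genes listed at 0 were chosen after the data were seen, and the reading of the albumin-scaled test was changed after its value was seen. The other tests and their readings were written before their values were computed, with the pattern they address already known.

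Of the genes called in untreated mice, each with 1 direction in all 3 untreated couples, 69 had the opposite direction in the antibiotic couple. The dependence on antibiotics was tested by limma and passed for none of them. With the 45 genes listed at 0 in the WT antibiotic library kept, it passed for Slc28a1 and Plet1 (both adjusted p = 0.0337). These passes rest on the ranks that doubtful genes listed at 0 took in the adjustment. Among the genes named in the text, the KO over WT log2 ratio with antibiotics was 2.19 for Pdk4, 0.96 for Fgf15, 0.87 for Aqp1, 0.63 for Adh1, 0.51 for Abcg8, 0.43 for Fbp1, 0.40 for Slc28a1, 0.33 for Ces1g, 0.31 for Slc47a1, 0.29 for Cda, 0.16 for Abcg5, 0.11 for Rdh7 and 0.02 for Lct, all lower in untreated KO. It was -0.86 for Ido1, -0.62 for Duox2, -0.50 for Plet1, -0.40 for Upp1, -0.26 for Tac1, -0.17 for Duoxa2, -0.17 for Trim15, -0.11 for Gsr and -0.04 for Slc6a14, all higher in untreated KO. Many of these ratios were small, in a pair without replicates, and do not show a reversal. Values in WT and KO with antibiotics were below 1 for Plet1 (0.588 and 0.119) and Slc6a14 (0.0296 and 0.00366).

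The smaller genotype differences in the antibiotic couple were weighed against faults of its WT column. On a scale with the untreated WT mean at 0 and the untreated KO mean at 1, the KO antibiotic library, whose column shows no such faults, had a median position of 0 over the called genes, where such faults alone would leave it near 1. KO libraries of couples held out of the calling, a comparison added later, had positions of 0.83 to 1.03. Variation of the size seen among the 3 untreated couples is also argued against. The slope of the antibiotic couple's ratios on the fold changes of a pair of untreated couples was at most 0.25, below the lowest held-out slope of 0.80 by more than 3 SD (SD 0.04). That SD rests on 3 slopes from overlapping pairs of couples, so it measures the spread between couples only roughly. Only 1 couple was given antibiotics, so an effect of the drugs cannot be told apart from a trait of this couple, its litter or its separate normalization. Milder disease in KO mice given antibiotics may be a biological candidate and stays untested.

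Liver transcripts appeared in 4 libraries. If liver RNA from a common source were present, its genes would keep their proportions, and the lowest Pearson r between these libraries across the 32 liver genes was 0.40 (genes are not independent replicates), between the bounds of 0.7 and 0.3 set for the test. Apoa2 was 37.4 in KO of couple 1 and listed at 0 in both antibiotic libraries, where albumin was 397 and 357 against 110; a listing at 0 may be a missing value, so the origin stays open. For 86.7% of the genes called higher with antibiotics (13 of 15), the rise exceeded the level in KO of couple 1 scaled by the albumin ratio of 3.42, and as first written the test would have counted this against liver RNA. It was then read as undecided, because the bound assumes the same liver profile in all of these libraries, which r = 0.40 does not give. No biological explanation was tested for the liver transcripts.

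Higher levels of short transcripts in untreated KO may reflect RNA fragmentation or library preparation, and the lists that moved were set against it. The ribosomal protein list lay at the 100th percentile (as rounded) of 10000 lists matched on exon length and mean level, whose median was 0.07 against 0.38 for the list. Random lists do not carry the correlation among ribosomal genes, so this percentile may overstate how unusual the list is. With the length trend removed, the PPARA target and xenobiotic medians were -0.71 and -0.93, at least 102% of their size before. The ribosomal median went from 0.38 to 0.31 and the interferon median from 0.69 to 0.59. Exon length bias is thus argued against as the whole cause of these changes, though it may be part of the ribosomal and interferon values, and other technical causes were not tested.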

How the results depend on the processing

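Alternatives that combine the replicate block with another choice, those that remove the length trend, and those of the antibiotic list counts, the blocked dependence and the left-out genes of the WT antibiotic library were chosen after seeing the data. Genes higher and lower in untreated KO numbered 135 and 118. With the replicate block they numbered 984 and 1161, with pseudocount 0.1 added to the block 989 and 1149, with pseudocount 5 907 and 1062, with quantile normalization 963 and 1128, and with the length trend removed 998 and 1051. The block gave 201 and 263 without couple 1, 200 and 221 without couple 2, and 248 and 275 without couple 3. Without the block, leaving out a couple gave 0 and 0 by limma (863 to 1370 genes at an unadjusted p under 0.05). No filter gave 7 and 4 (1936 genes at an unadjusted p under 0.05 against 1871), a mean of at least 5 gave 82 higher, and leaving out 1 library gave 41 to 74 higher and 21 to 69 lower. Other settings stayed within 1.5 times of 135 and 118, but the replicate block over all 4 couples (143 and 154) kept only 88 of the 247 earlier calls it tested. Cftr kept its direction throughout, and its adjusted p rose to 0.0751 without a filter (log2 change -1.50) and to 0.114, 0.0761 and 0.172 without couples 1, 2 and 3 (-1.50, -1.45 and -1.54).

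Gene lists called higher and lower (15 and 15) fell to 0 and 0 with an estimated correlation and to 7 and 5 with fry, and the block added the Paneth cell list (adjusted p = 0.0193). The antibiotic effect (15 higher, 3 lower) gave 1 lower with quantile normalization or median scaling, 8 lower with pseudocount 0.1, 0 and 0 without a filter or with the couple as a random block, and 5 to 14 higher and 1 to 6 lower without 1 library; its list counts of 11 and 10 were 0 and 0 with an estimated correlation and 16 lower with quantile normalization. The cause of these moves was not tested. The dependence count was 5 higher and 1 lower with the genes listed at 0 in the WT antibiotic library kept, and 0 in every other alternative run. Keeping them moved list medians in the antibiotic couple by at most 0.09. The percent of called genes with the untreated direction in the antibiotic couple was 71.3 to 72.1. For the other named genes, 376 of 498 values kept their call, 122 lost it and 0 reversed; with 1 library left out, 104 of 144 kept it and 40 lost it. The block changed no call of the genes named for the untreated comparison. Read depth is unknown, so its limit on low genes cannot be given.

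Of the 10 splits of the 6 untreated libraries into 3 and 3, 1, the real one, gave as many genes (253, highest other 0) and 1 as many lists (30, highest other 25). Of the 4 ways to swap genotypes within couples, 1 gave as many blocked genes (2145, highest other 0). These splits are too few for a share under 0.05. The 3 other splits that part all couples called 21 to 25 lists, and those that keep a couple together called 9 to 20, so camera with its preset correlation calls many lists in any grouping of these libraries.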

Other observations

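Among the 27 tested NRF2 and glutathione genes, 1 was lower and 1 higher in untreated KO ileum (5 lower and 9 higher with the couple block). Catalase (Cat), a peroxisomal enzyme, went from 188 ± 49.9 to 51.4 ± 12.2 (SD, n = 3 each; limma adjusted p = 0.0195), while glutathione reductase (Gsr) went from 63.7 ± 7.22 to 133 ± 3.65 (adjusted p = 0.0319). The glutathione peroxidase Gpx2 was 142 ± 39.9 and 574 ± 262 (adjusted p = 0.0761, and 0.0163 with the couple block). Cat had a log2 change of -1.70, -1.97 and -1.85 in couples 1, 2 and 3.

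Further genes with opposite directions in the antibiotic couple were chosen after their values were seen. Aqp1 was 112 in untreated WT and 35.7 in untreated KO ileum on average, and 104 and 190 with antibiotics. Ido1, an interferon-induced enzyme of tryptophan breakdown, was 5.83 and 23.3, and 4.62 and 2.1 with antibiotics. Duox2 was 10.6 and 53, and 6.14 and 3.65 with antibiotics.

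Couple 2, the male couple, stood apart for some abundant transcripts in both genotypes. The mitochondrial transcript mt-Nd6 was 195 and 171 in couple 2 and between 1430 and 1850 in the other 4 untreated libraries. Gapdh was 68.2 and 83.2 against 9.81 to 18.1, and Actb 3060 and 2400 against 893 to 1240. The cause was not tested, and the instrument of each library is not given.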
